A study of Rattus norvegicus with 24 samples.

How the data were processed

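Liver RNA of 24 male Wistar rats was measured on Affymetrix whole-transcript arrays, 1 array per rat and 1 colour. Per the labels, labelled cDNA was made from total RNA with no reduction of ribosomal RNA, and carried biotin. The rats ate a diet with 5% or 20% protein for 1 or 4 weeks, which gives 4 groups of 6. These are the percentages and times of the titles; the description codes hold 4 and 18 in place of 5 and 20, and the design text gives 4 weeks only, so the percentages and times are in some doubt. The deposited values are intensity of probe sets after RMA (robust multi-array average: background subtraction, quantile normalization and summary over probes), given by the authors on the unlogged scale. The submitters' processing notes name RMA without a version, and no filter is stated. The values ran from 3.27 to 15793, none was missing, and no 2 arrays held the same values. RMA values carry no background measure or detection call, so no detection limit is given, and a fold change against a group near the low end of the scale cannot be bounded. For arrays, their number limits the precision.

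The log2 of the intensity was used. Of 29214 probe sets, 18644 paired with 1 gene symbol, 962 with several and 9608 with none, and the last 2 kinds were left out. Where a gene had more than 1 probe set (871 genes), the one with the highest mean over all arrays was kept, which left 17245 genes. Symbols are those of the array annotation, and 17108 were looked up by Entrez identifier in a RefSeq table, where 0 differed. The files name no genome build, so no positions are given.

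The 4 group means were fitted in 1 linear model with limma 3.58.1 (lmFit and eBayes, no trend, not robust) in R 4.3.3 with data.table (version 1.17.8). The model had 20 residual degrees of freedom and a prior of 3.95. The comparisons were 5% minus 20% protein at 1 week and at 4 weeks, the difference between these effects (diet by time), and 4 weeks minus 1 week on each diet. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the 17245 genes, two-sided, and adjusted p values of genes below are from limma. "Rose" and "fell" in a diet comparison mean called higher and called lower on 5% protein. Errors are standard errors of the fitted log2 difference, or SD where so marked, with n = 6 animals per group. Counts of genes whose groups did not overlap are given beside the number that chance gives. No paired analysis was possible because the labels give no animal number to more than 1 group.

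For 48 lists (35 gene lists and 13 lists of cell type markers), limma's camera compared the members with all other genes at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 48 lists within a comparison. The same test with the correlation estimated from the data, and limma's fry, were run beside it. fry asks whether a list's genes move, on balance, in 1 direction, and does not compare them with other genes. Of 1105 entries of the lists, 961 were measured. Members called after adjustment within their list are given as "adjusted over the list alone".

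The model, the comparisons, the lists and the rule for named genes were chosen before the data were examined. The rule took a fixed set of genes for both diet comparisons, the 5 largest rises and falls among called genes whose groups did not overlap, the 2 members of each called list with the smallest p in the list's direction, the 4 largest differences in each direction for diet by time, and the 3 largest rises and falls for each time comparison. Other list members named as examples, and the genes named for the runs, were picked after their values were seen. Some of the fixed genes, Cyp4a1, Fasn and Srebf1 among them, were not analysed here, because the annotation used here pairs no probe set with them alone.

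The labels name no batch, but the titles hold a well position and an animal number. The animal numbers fall into 4 runs. The first (22 to 32) and the third (59 to 73) were fed for 4 weeks, the second (49 to 54) and the fourth (74 to 79) for 1 week. Each 1 week group has 3 animals in each of its runs. At 4 weeks, 5 of the 5% animals and 2 of the 20% animals are in the first run, and 1 and 4 in the third. The diet comparisons were fitted again within each run, from 1 model of the means of each group and run, so that all 24 animals share the estimate of the spread. Where a run held 1 animal of a diet, its spread was taken to be that of the others.

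The alternatives tried were quantile normalization between arrays, centring of array medians, an offset of 16 before log2, the mean over a gene's probe sets, every probe set tested, the lowest 33.3% of genes left out, eBayes with trend and robust estimation, array weights, only the 2 groups compared, well column as a covariate, run within its week as a covariate, well row as a random block, each run alone, and each animal left out in turn. Leaving out either run's 3 animals from the 20% group at 1 week was added after seeing the data. Each comparison was also run on 100 splits of the animals into groups of the same sizes, the real one included, drawn with a fixed seed. On simulated data, drawn with each gene's own mean and spread and with changes added to the 5% animals at 1 week, limma called 96% of 100 genes changed by 1 on the log2 scale and 64% of 100 changed by 0.5, with 9 unchanged genes among 169 called. The list test found the shifted list and 0 others. The simulated genes were drawn independently of each other, so this does not show how the list test behaves where genes are correlated. Principal components and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.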

Results

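Gene expression was measured in the livers of 24 male rats on whole-transcript arrays. The animals were fed 5% or 20% protein for 1 or 4 weeks, with 6 animals in each of the 4 groups. The series title concerns fatty liver, peroxisomes, mitochondria and ATP in malnutrition, and a rescue by the drug fenofibrate. Fenofibrate samples were not analysed here, since all 24 arrays come from animals given only the diets. The array medians lay between 42.4 and 45.5 in intensity, and arrays of the same group correlated at 0.984 to 0.995 across probe sets. The values of 17245 genes entered the comparisons, and the median standard error of a diet difference was 0.10 on the log2 scale.

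The first principal component, with 33.7% of the variance, parted the diets. The second, with 11.6%, parted the 20% animals at 1 week by their run of animal numbers. Between those runs of 3 and 3 animals, 742 genes were higher and 1126 lower in the later run, against 59 and 76 in the 5% animals of the same week. At 4 weeks the 20% animals differed between runs in 145 and 165 genes. For the 5% animals at 4 weeks, where the third run held 1 animal, limma called 0 genes between the runs and 971 had an unadjusted p below 0.05.

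**Figure D1:**
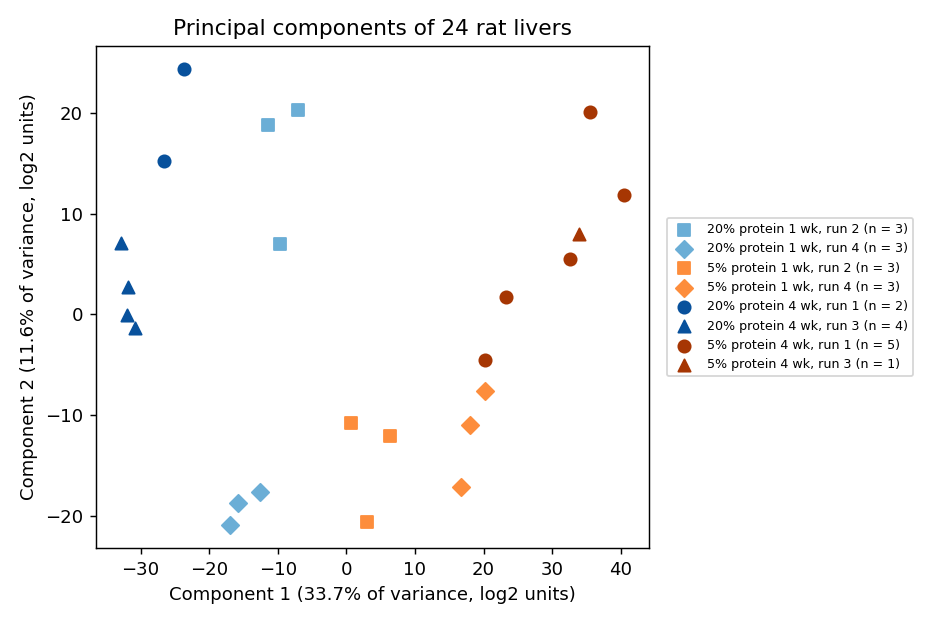
Scores of the 24 livers on the first and second principal components of log2 intensity, with each component's share of the variance on its axis. Colour gives the group and shape the run of animal numbers; the 20% animals at 1 week lie apart by run on component 2, from 6.99 to 20.29 in the earlier run and from -20.97 to -17.70 in the later.

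The comparison of diets at 1 week asks how the liver responds early to a shortage of protein. Genes induced by lack of amino acids were higher on 5% protein. Trib3, a pseudokinase of the amino acid stress response (probe set 10850775), rose by 2.95 ± 0.41 on the log2 scale, from a mean log2 intensity of 6.05 ± 0.34 to 9.0 ± 1.38 (SD, n = 6). Slc7a1, a transporter of cationic amino acids, rose by 2.23 ± 0.27. Igfbp1, a secreted binding protein of insulin-like growth factors, rose by 3.20 ± 0.64, a 9.18-fold change, while Igf1 itself fell by 0.47 ± 0.08. The axon guidance receptor gene Unc5b rose by 2.76 and Serpina7, which encodes thyroxine-binding globulin, by 2.17. Among called genes whose diets did not overlap, the largest falls were those of Rup2, a urinary protein gene (-3.74 ± 0.92), Car3, a carbonic anhydrase (-3.0 ± 0.53), Ugt2b, a glucuronosyltransferase (-2.67), Sds, which breaks down serine (-2.61), and Cyp3a73, a cytochrome P450 (-2.44). Trib3, Slc7a1, Igfbp1, Unc5b and Serpina7 were the 5 largest rises among the same kind of genes. In these 10 genes all 6 animals on 5% lay on 1 side of all 6 on 20%, because they were picked by that rule.

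Targets of ATF4, the transcription factor of the amino acid response, rose as a group at 1 week. Of 35 measured members 17 rose and 1 fell (18 and 1 adjusted over the list alone), with a median log2 change of 0.48 (adjusted p = 6.70e-16, and adjusted p = 0.0383 with an estimated correlation). Among them were Nupr1 (1.12 ± 0.12), the liver hormone gene Fgf21 (2.21 ± 0.54), Asns, asparagine synthetase (1.88 ± 0.48), and Ddit3, the stress factor CHOP (0.97 ± 0.20). Psat1 of serine synthesis did not pass the test (1.32 ± 0.44, adjusted p = 0.0945). Cytosolic ribosomal protein genes also rose, 15 of 26 (20 adjusted over the list alone) with a median of 0.31 (adjusted p = 5.84e-22, and adjusted p = 0.0383 with an estimated correlation). Rplp0 rose by 0.38 ± 0.06 and Rps19 by 0.64 ± 0.10.

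Genes of cell division were lower on 5% at 1 week, with 8 of 32 fallen (20 adjusted over the list alone) and a median of -0.59 (adjusted p = 0.349 with an estimated correlation). The median was -0.27 in the second run of animal numbers (2 fell) and -0.96 in the fourth (21 fell), where the 20% animals had higher cell cycle genes. Mcm4, part of the helicase of DNA replication, fell by 0.85 ± 0.19 and Aurka, a kinase of mitosis, by 0.53 ± 0.12. Of 7 erythroid markers 3 fell (6 adjusted over the list alone), with a median of -1.25 (adjusted p = 0.349 with an estimated correlation). They included Ahsp (-1.41 ± 0.39), a chaperone of haemoglobin, and Epb42 (-0.55 ± 0.15) of the red cell membrane. Sex-biased genes that depend on growth hormone fell in 6 of 18 (7 adjusted over the list alone), with a median of -0.73 (adjusted p = 0.0788 with an estimated correlation). Cyp2c11, the main male-specific P450 of rat liver, fell by 3.16 ± 0.74, and the hydroxyacid oxidase gene Hao2 changed by -2.79 ± 0.63.

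Urea cycle and amino acid breakdown genes fell in 5 of 44 (10 fell and 1 rose adjusted over the list alone), with a median of -0.14 (adjusted p = 0.876 with an estimated correlation). The median was 0.02 in the second run (adjusted p = 0.744) and -0.38 in the fourth, and the list did not pass without 20% animal 77 (-0.11, adjusted p = 0.0973). Besides Sds they included Cbs of cysteine synthesis (-1.22 ± 0.20) and Oat, ornithine aminotransferase (-1.64 ± 0.36). Of 12 pericentral hepatocyte markers 2 fell, Oat and Gstm1 (-0.52 ± 0.07), and the same 2 of 12 adjusted over the list alone (list median -0.22, adjusted p = 0.665 with an estimated correlation, and adjusted p = 0.418 in the fourth run). Proteasome genes fell in 2 of 29 (2 adjusted over the list alone), Psmb3 (-0.38) and Psma1 (-0.28), with a list median of -0.11 (adjusted p = 0.729 with an estimated correlation). The median was -0.21 in the second run (7 fell) and -0.004 in the fourth (0 fell, adjusted p = 0.931). The call was lost under quantile normalization (-0.08, adjusted p = 0.0692; Psma1 0.0508) and without 20% animal 53 (-0.06, adjusted p = 0.142) or 77 (-0.09, adjusted p = 0.0544). In gluconeogenesis and glycolysis 1 of 17 rose (1 adjusted over the list alone), Pck2 by 0.93 ± 0.15, with a list median of 0.16 (adjusted p = 0.386 with an estimated correlation). That list did not pass in the fourth run (0.01, adjusted p = 0.603), nor without 5% animal 49 (adjusted p = 0.0690) or 20% animal 53 (adjusted p = 0.0771). Pck2 makes phosphoenolpyruvate in mitochondria, and its cytosolic counterpart Pck1 did not pass (0.14 ± 0.40).

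Of the lists for peroxisomes and mitochondria 1 passed at 1 week over all 12 animals, that of mitochondrial biogenesis. Several had unlike medians in the 2 runs of animal numbers, each run tested alone, with no list test of the difference given here. Complexes II to V were at 0.24 in the second run (7 rose, adjusted p = 3.30e-08) and -0.22 in the fourth (5 fell, adjusted p = 2.87e-06), complex I at 0.14 (6 rose, adjusted p = 3.71e-05) and -0.24 (7 fell, adjusted p = 4.48e-06), and peroxisomal enzymes at 0.02 (1 fell, adjusted p = 0.370) and -0.22 (6 fell, adjusted p = 0.000546). Of 19 peroxisome biogenesis genes 0 rose and 1 fell (2 and 2 adjusted over the list alone), and of 34 enzymes of peroxisomal lipid oxidation and antioxidant defence 0 rose and 4 fell (0 and 4 adjusted over the list alone). Neither list passed (adjusted p = 0.455 and 0.135). Targets of PPARa, the receptor through which fenofibrate acts, rose in 2 of 27 (2 adjusted over the list alone), Fgf21 and Hadhb, with an adjusted p of 0.277 for the list. Over all 12 animals limma called 0 of 33 subunits of complex I in either direction. Mitochondrial biogenesis genes passed as a list with a median of 0.08 and 0 of 25 called (2 rose adjusted over the list alone), and lost the call with an estimated correlation (adjusted p = 0.349) and in the second run (0.02, adjusted p = 0.744; 0.22, 4 risen and adjusted p = 0.00260 in the fourth), with fry (adjusted p = 0.0530), with well row as a random block (adjusted p = 0.0602), with every probe set tested (adjusted p = 0.0621), and without 5% animal 74, 75 or 76 or 20% animal 78 (adjusted p from 0.0519 to 0.0929). Cat, Pex5, Pex11a, Pex14, Ppara, Ehhadh, Cpt1a and Ppargc1a did not pass at 1 week, with log2 differences from -0.33 (Cpt1a) to 0.65 (Ppargc1a), nor did Scd (0.21), Cyp7a1 (0.72), Alb (-0.04) and Cps1 (-0.30).

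At 1 week limma called 321 genes higher and 420 lower on 5% protein, 129 and 172 of them by at least 1.5-fold, and 3052 genes had an unadjusted p below 0.05. With well row as a random block the counts were 168 and 168. At 1 week no well row held both diets, with 5% in rows C, E and G and 20% in D and H. The diet comparison there is thus also one between rows, and a batch of rows cannot be told apart from diet. The diets did not overlap in 441 of the 17245 genes tested, called or not. By chance, 37.3 of the 17245 genes (0.216%) would part in this way. Within runs, with 3 animals per diet, 494 and 812 genes were called in the second run and 696 and 768 in the fourth. By limma's test of the difference, the diet effect itself differed between these 2 runs in 1258 genes. Unfolded protein response genes went opposite ways there, by -0.37 in the second run (11 fell and 2 rose, adjusted p = 1.11e-06) and 0.31 in the fourth (11 rose, adjusted p = 2.87e-06). Without 5% animal 74 the counts at 1 week were 213 and 205.

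The comparison at 4 weeks asks what a longer shortage does, with peroxisomes and mitochondria in view. Enzymes of peroxisomal lipid oxidation and antioxidant defence moved in both directions, 15 of 34 down and 6 up (18 and 6 adjusted over the list alone), with a median of -0.22. The list passed (adjusted p = 0.0143), but not with an estimated correlation (adjusted p = 0.516). Xdh, which makes uric acid and hydrogen peroxide, fell by 1.89 ± 0.15, and the glycolate oxidase gene Hao1 by 0.83 ± 0.11. Acox2 and Amacr, which act on branched chains and bile acid precursors, fell by 1.35 ± 0.18 and 1.12 ± 0.23, and Cat, catalase, by 0.21 ± 0.06. Higher were the transporter of very long chain fatty acids Abcd2 (2.15 ± 0.40) and the carnitine acyltransferases Crat (1.78 ± 0.34) and Crot (1.14 ± 0.23). Of 19 peroxisome biogenesis genes 3 rose and 4 fell (3 and 4 adjusted over the list alone), and the list did not pass (median 0.00, adjusted p = 0.889). Pex11a, a factor of peroxisome division (probe set 10722982), rose by 1.15 ± 0.36 and Pex14 of the import machinery by 0.34 ± 0.08. The import receptor gene Pex5 fell by 0.44 ± 0.14 and the membrane protein gene Pxmp2 by 0.88 ± 0.17.

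PPARa targets rose as a list at 4 weeks, 10 up and 5 down of 27 (11 and 5 adjusted over the list alone), with a median of 0.24. Its adjusted p was 0.00741 (adjusted p = 0.462 with an estimated correlation). The acyl-CoA thioesterase genes Acot1 and Acot2 rose by 5.31 ± 0.68 and 1.99 ± 0.20, Hadhb of fatty acid oxidation by 1.20 ± 0.10, and Fgf21 by 3.66 ± 0.54. Fabp1, a fatty acid carrier, fell by 0.79 ± 0.14, and Acadm, a dehydrogenase of medium chains, by 0.47 ± 0.12. Ppara itself did not pass (0.05 ± 0.21), nor did Ehhadh (0.52 ± 0.25, adjusted p = 0.128) or Cpt1a (0.07 ± 0.38). In mitochondrial fatty acid oxidation 3 of 21 rose and 6 fell (3 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.687).

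Genes of mitochondrial biogenesis and dynamics rose in 16 of 25 and fell in 1 (19 and 1 adjusted over the list alone), with a median of 0.32 (adjusted p = 4.53e-08, and adjusted p = 0.00674 with an estimated correlation). Ppargc1a, a coactivator of mitochondrial genes, rose by 1.56 ± 0.28. The mitochondrial proteases Lonp1 and Clpp rose by 1.49 ± 0.16 and 0.79 ± 0.07, and Tfam, which maintains mitochondrial DNA, by 0.34 ± 0.09. Fis1, of mitochondrial and peroxisomal fission, fell by 0.44 ± 0.14. Few subunits of the respiratory chain were called. Of 33 in complex I 2 rose and 4 fell (2 and 4 adjusted over the list alone), and of 38 in complexes II to V 3 rose and 1 fell (3 and 1 adjusted over the list alone). Neither passed as a list (adjusted p = 0.689 and 0.627), though complexes II to V did in the first run (0.16, adjusted p = 0.00257; 0.06 and 0.891 in the third).

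The amino acid response had a larger median at 4 weeks (the difference is tested under diet by time). Of 35 ATF4 targets 25 rose and 2 fell (25 and 2 adjusted over the list alone), with a median of 1.21 (adjusted p = 4.12e-15, and adjusted p = 0.0237 with an estimated correlation). Trib3 rose by 4.90 ± 0.41, Slc7a1 by 3.58 ± 0.27, Aldh18a1 of proline synthesis by 2.88 ± 0.20, Asns by 3.44, Psat1 by 2.54 and Ddit3 by 1.36. All 26 ribosomal protein genes rose (26 adjusted over the list alone), with a median of 0.65 (adjusted p = 9.23e-26, and adjusted p = 0.0129 with an estimated correlation), Rplp0 by 0.78 ± 0.06 and Rps19 by 1.10 ± 0.10. Amino acid breakdown genes fell in 25 of 44 (25 fell and 1 rose adjusted over the list alone), with a median of -0.49 (adjusted p = 0.186 with an estimated correlation). Cps1, the entry enzyme of the urea cycle, fell by 0.71 ± 0.10, Hal of histidine breakdown by 1.64 ± 0.17 and Cbs by -1.87 ± 0.20. Periportal markers fell in 7 of 14 and rose in 2 (7 and 2 adjusted over the list alone), with a median of -0.55 (adjusted p = 0.344 with an estimated correlation). Of the 7 that fell, all but Aldh1b1 (-1.90) are in the amino acid breakdown list too, Cps1 and Hal among them. The 2 lists are thus not separate evidence. Hsd17b13 (0.34) and Sox9 (0.66) rose.

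Sex-biased liver genes showed some of the largest falls at 4 weeks. Of 18 sex-biased genes 10 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -1.39 (adjusted p = 1.36e-06, and adjusted p = 0.0166 with an estimated correlation). Stac3 (probe set 10895915) fell by 7.02 ± 0.28, from a mean log2 intensity of 11.56 ± 0.82 to 4.55 ± 0.16 (SD, n = 6). The urinary protein genes Rup2 and Mup5 fell by 5.83 ± 0.92 and 4.89 ± 0.17, and Cyp2c11 by 5.73 ± 0.74. The gene that rose was Cyp2c12, the female-specific P450 of rat liver (2.96 ± 0.25), while Cyp2c7 and Sult2a1, which are female-biased in rats, changed by -3.10 and -2.77. Dhrs7l1, a dehydrogenase gene, fell by 6.33 ± 0.53 and Car3 fell by 5.39 ± 0.53. Xenobiotic P450 genes fell in 8 of 19 and rose in 2 (10 and 2 adjusted over the list alone), with a median of -0.49 (adjusted p = 0.344 with an estimated correlation), Cyp3a9 by -2.50 ± 0.29, though that list did not pass in the third run of animal numbers (-0.31, adjusted p = 0.107; -0.66 in the first), while Cyp2b1 and Cyp2b2 rose by 2.04 and 2.49. The Cyp2, Gsta, Acot and urinary protein genes belong to families of close copies whose probes can share signal.

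Genes of lipoprotein assembly, plasma proteins and the acute phase fell as lists at the preset correlation, but not with an estimated one. In lipoprotein assembly and lipid uptake 12 of 20 fell and 2 rose (14 and 2 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.345 with an estimated correlation). The hepatic lipase gene Lipc fell by 1.16 ± 0.12 and the receptor gene Lrp1 by 1.04 ± 0.13, while Mttp, which loads lipid onto apolipoprotein B, rose by 0.27 ± 0.07 and Vldlr by 2.41 ± 0.19. Scd, a fatty acid desaturase, fell by 1.05 ± 0.35. Plasma protein genes fell in 16 of 23 and rose in 1 (18 and 1 adjusted over the list alone), with a median of -0.28 (adjusted p = 0.377 with an estimated correlation). Igfals, which stabilises circulating IGF1, fell by 2.98 ± 0.31 and Itih1 by 0.95 ± 0.09, whereas Alb, albumin, did not pass (-0.13 ± 0.06, adjusted p = 0.0869). Of 20 acute phase genes 13 fell (13 fell and 1 rose adjusted over the list alone), with a median of -0.40 (adjusted p = 0.344 with an estimated correlation), Orm1 by -2.96 ± 0.35 and Crp by -0.45 ± 0.07. Igf1 fell by 0.70 ± 0.08 and Igfbp1 rose by 4.57 ± 0.64. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and Pck1 did not pass (1.25 ± 0.98 and -0.59 ± 0.40).

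Genes of glutathione metabolism and NRF2 targets rose in 13 of 28 and fell in 3 (15 and 4 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.183 with an estimated correlation). The glutathione transferase gene Gsta3 rose by 4.59 ± 0.19 and the export pump gene Abcc3 by 3.50 ± 0.20. Growth arrest genes rose in 5 of 13 (6 rose and 1 fell adjusted over the list alone), with a median of 0.27 (adjusted p = 0.0453, and adjusted p = 0.345 with an estimated correlation), among them Gadd45a (1.92 ± 0.26) and Tp53inp1 (1.07 ± 0.23). That list did not pass without 20% animal 29, 30 or 63 or 5% animal 31 or 32 (adjusted p from 0.0548 to 0.0944), nor in the third run of animal numbers (0.11, adjusted p = 0.321), with array medians centred, the lowest genes left out, every probe set tested or array weights (adjusted p from 0.0509 to 0.102). Unc5b rose by 5.00 ± 0.41.

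Macrophage and stellate cell markers and matrix and interferon genes were lower as lists at 4 weeks. Markers of T and NK cells, of B and plasma cells and of neutrophils did not pass (adjusted p = 0.125, 0.0549 and 0.689). Of 15 macrophage markers 11 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.50 (adjusted p = 0.344 with an estimated correlation), C1qa by -0.79 ± 0.13 and Msr1 by -0.50 ± 0.08. Interferon response genes fell in 12 of 22 and rose in 1 (15 and 1 adjusted over the list alone), with a median of -0.75 (adjusted p = 0.451 with an estimated correlation), Stat2 by -1.08 ± 0.13 and Rig1 by -0.96 ± 0.12. Matrix genes fell in 14 of 23 (18 adjusted over the list alone), with a median of -0.54 (adjusted p = 0.345 with an estimated correlation), Loxl2 by -0.87 ± 0.13 and Sparc by -0.80 ± 0.13. Of 13 stellate cell markers 4 fell (7 adjusted over the list alone), with a median of -0.36 (adjusted p = 0.344 with an estimated correlation), Rgs5 by -1.08 ± 0.17 and Colec11 by -0.31 ± 0.08. The stellate list did not pass without 20% animal 30 (-0.32, adjusted p = 0.0792), where the erythroid list was at -0.78 and just missed the threshold, nor the interferon list in the third run (-0.34, adjusted p = 0.228). Erythroid markers fell in 3 of 7 (5 adjusted over the list alone), with a median of -1.05 (adjusted p = 0.451 with an estimated correlation), the haemoglobin genes Hbb and Hbb-b1 by -1.90 ± 0.41 and -1.87 ± 0.35. The markers of macrophages, stellate cells and red cells were thus lower in the same group as the interferon, matrix and acute phase genes. Whether they varied together from animal to animal was not tested.

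**Figure D2:**
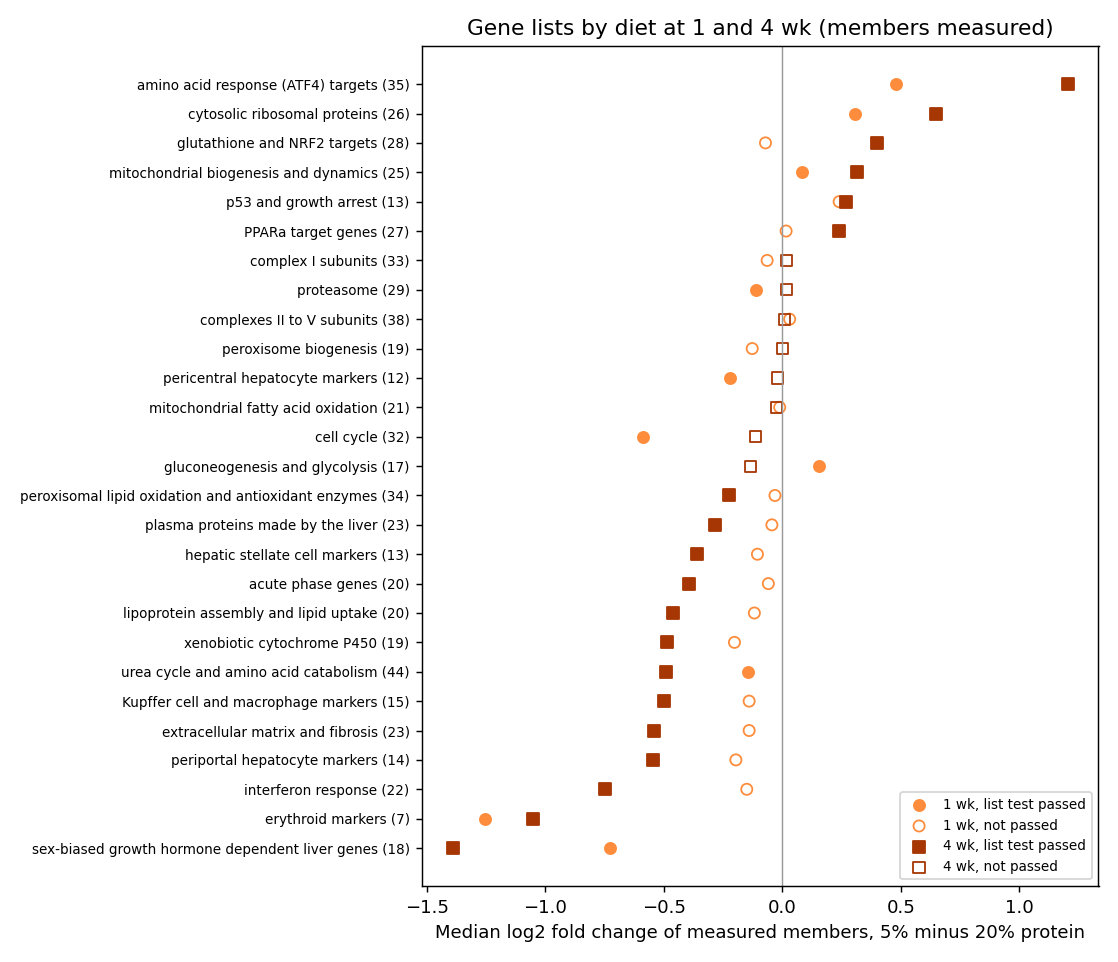
Median log2 fold change of the measured members of each list (5% minus 20% protein) at 1 week (circles) and 4 weeks (squares), for lists that passed the list test at either time and for the peroxisome and mitochondrial lists. Filled marks passed at the preset correlation, and number of members is in brackets; ATF4 targets lie at 0.48 and 1.21, sex-biased genes at -0.73 and -1.39.

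At 4 weeks limma called 2308 genes higher and 2147 lower, 25.8% of all, 971 and 828 of them by at least 1.5-fold, and 6103 had an unadjusted p below 0.05. The runs hold unequal numbers of each diet, so diet and run are partly mixed. With run as a covariate 3681 genes were called, and 3289 of them were among the 4455. In 2143 of the 17245 genes tested, called or not, the diets did not overlap, against 37.3 by chance. Within runs, 1434 and 1300 genes were called in the first and 1178 and 946 in the third, where 1 animal ate 5% protein. The PPARa median was 0.51 in the first run (adjusted p = 0.000416) and -0.05 in the third (0.484), the peroxisomal enzyme median -0.14 (0.253) and -0.35 (0.000199), and that list's call was lost without 5% animal 23.

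The effects at the 2 times overlapped. Of the called genes 240 were higher on 5% at both times, against 43.0 if the calls were independent, 272 were lower at both, against 52.3, and 3 went opposite ways. Across genes, which are not independent replicates, the log2 changes correlated at 0.61 (Pearson) and 0.40 (Spearman). Of the 741 genes called at 1 week 699 had the same sign at 4 weeks, and 403 were larger in size then. The median size was 0.52 at 1 week and 0.54 at 4 weeks. These genes were chosen by their call at 1 week, which tends to raise their size there but not at 4 weeks. The sizes therefore do not show whether the effects grew. With well row as a random block the overlap was 136 higher and 122 lower, and without 5% animal 74 at 1 week 150 were lower at both.

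Diet by time asks which diet effects differed between 1 and 4 weeks. The effect at 4 weeks exceeded that at 1 week most for Acot1 (by 4.88 ± 0.96), Gsta3 (3.64 ± 0.27), Ccdc92 (3.38 ± 0.60) and C1h11orf86 (3.35 ± 0.79). It was more negative for Stac3 (-6.52 ± 0.40), Mup5 (-4.91 ± 0.24), Dhrs7l1 (-4.52 ± 0.75) and Nox4, an oxidase that makes hydrogen peroxide (-3.50 ± 0.46). For Stac3 and Mup5 the mean log2 intensity was below the array medians in each group except 20% at 4 weeks, where it was 11.56 and 8.19. Ribosomal protein genes differed in 14 of 26, all more positive at 4 weeks (19 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.187 with an estimated correlation). Amino acid breakdown genes were more negative in 12 of 44 (19 adjusted over the list alone, and 1 more positive), with a median of -0.40 (adjusted p = 0.336 with an estimated correlation). ATF4 targets differed in 7 of 35, all upwards (14 adjusted over the list alone), by a median of 0.55 (adjusted p = 0.336 with an estimated correlation), and mitochondrial biogenesis genes in 4 of 25, all upwards (7 adjusted over the list alone), by 0.26 (adjusted p = 0.0420 with an estimated correlation). Of 48 lists, 7 differed upwards and 15 downwards at the preset correlation, but 1 of these 22 with an estimated correlation, and fry called 7.

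Limma called 611 genes with a more positive and 380 with a more negative effect at 4 weeks, 407 and 266 by at least 1.5-fold. With run as a covariate the counts were 311 and 175, and 413 of the 991 genes were shared. They were 1198 and 603 without the later run's 20% animals at 1 week (444 and 235 without the earlier run's), and ran from 360 to 890 and from 219 to 519 when 1 animal was left out.

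**Figure D3:**
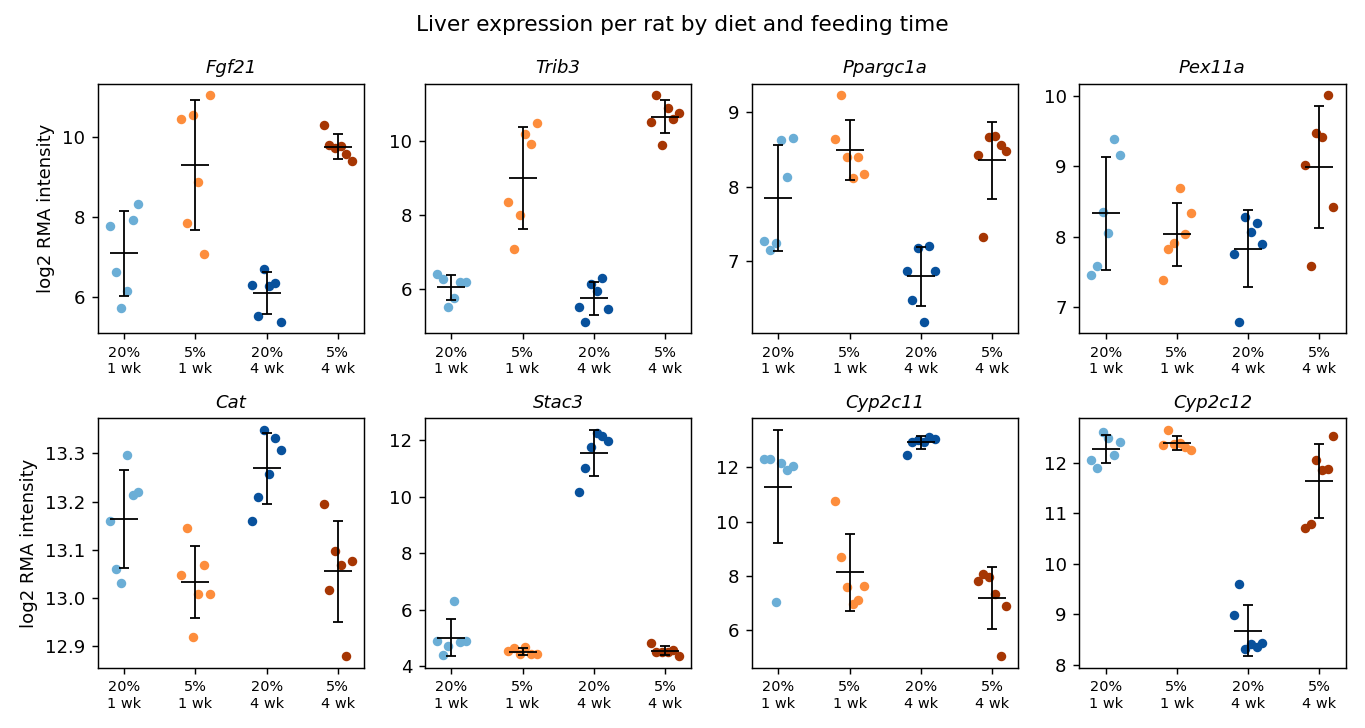
Log2 RMA intensity of 8 genes in each rat, by diet and feeding time, with the mean (long bar) and SD (whiskers) of each group of 6. Stac3 lies at 11.56 on average on 20% at 4 weeks and near 4.5 to 5.0 in the other groups, and the vertical scale differs between panels and does not start at 0.

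The time comparisons ask what changed between 1 and 4 weeks on each diet. On 20% protein Stac3 rose by 6.54 ± 0.28, Dhrs7l1 by 5.80 ± 0.53 and Hsd3b5, a steroid dehydrogenase gene, by 5.02 ± 0.56. H19, an imprinted RNA of fetal liver, fell by 4.19 ± 0.67, Cyp2c12 changed by -3.59 ± 0.25 and Abcd2 by -3.32 ± 0.40. Sex-biased genes rose in 6 of 18 and fell in 1 (6 and 1 adjusted over the list alone), with a median of 1.01 (adjusted p = 1.58e-06, and adjusted p = 0.0196 with an estimated correlation). PPARa targets fell in 5 of 27 (10 adjusted over the list alone), with a median of -0.47 (adjusted p = 0.290 with an estimated correlation), and mitochondrial biogenesis genes in 4 of 25 (5 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.0196 with an estimated correlation).

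On 5% protein Hsd3b5 rose by 5.19 ± 0.56, Cyp2c13, a male-biased P450, by 3.44 ± 0.75 and Ugt2b by 3.24 ± 0.76. Spink1l fell by 2.64 ± 0.50, Aspg, an asparaginase gene, by 2.34 ± 0.34 and the fructose transporter gene Slc2a5 fell by 2.25 ± 0.37. Stac3 did not pass on this diet (0.02 ± 0.28), and neither did Cyp2c12 (-0.76 ± 0.25, adjusted p = 0.0650). Macrophage markers fell in 8 of 15 (13 adjusted over the list alone), with a median of -0.54 (adjusted p = 0.250 with an estimated correlation). Amino acid breakdown genes fell in 14 of 44 (17 adjusted over the list alone), with a median of -0.26 (adjusted p = 0.356 with an estimated correlation), and gluconeogenesis and glycolysis genes in 6 of 17 (6 adjusted over the list alone), with a median of -0.43 (adjusted p = 0.250 with an estimated correlation).

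Limma called 176 genes higher and 259 lower at 4 weeks on 20%, and 716 and 713 on 5%. Of these, 19 were higher on both diets (7.31 if independent), 31 lower on both (10.7) and 14 went opposite ways, with correlations across genes of 0.06 (Pearson) and -0.07 (Spearman). Each run of animal numbers was fed for 1 time only, so no time comparison could be made within a run, and a batch of runs cannot be told apart from time. With well row as a random block 81 genes were higher on 20%, without the later run's animals at 1 week 293 were higher and 695 lower there, and without animal 67 the counts were 113 and 151, while those on 5% were 403 and 386 without animal 32.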

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

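The tests of blood by the erythroid level of other animals, of close gene copies and of the share of non-hepatocyte cells were chosen only after the result was seen.

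The 20% animals at 1 week parted by run of animal numbers in 1868 genes, with 16 of 32 cell cycle genes higher (median 0.76) and 14 of 26 unfolded protein response genes lower (median -0.55) in the later run, and Cyp7a1 lower by a log2 of -4.70 ± 0.83. A batch of RNA or array processing that acts on both diets alike is argued against by the 5% animals of the same week, whose run difference correlated at -0.0155 across genes with that of the 20% animals. The run differences of the 20% animals at 1 and at 4 weeks correlated at 0.487, so part of the pattern may be shared by the runs on that diet. Time of day or feeding state at sampling stays open: 7.14% of the 14 clock genes were called (1 gene, Per2; exact 95% binomial interval 0.181% to 33.9%), which is under the bound of 10% set beforehand, but that interval is wide, and Per2 and the heat shock genes Hsph1, Stip1, Chordc1 and Bag3 were lower in the later run on 20% at 4 weeks too. No test of feeding state apart from the clock genes was run. In the later run 8 of 18 fatty acid synthesis genes (median 0.68) and 8 of 19 cholesterol synthesis genes (0.70) were higher, and 0 of either were lower. Between runs, these medians were 0.28 and 0.96 in the 5% animals of the same week, and -0.17 and 0.09 on 20% at 4 weeks. RNA of pancreas, fat or muscle is argued against by their markers, at -0.13, -0.02 and 0.00. Erythroid markers were higher in the later run by a median of 0.491 (95% bootstrap interval 0.103 to 0.913), but by 0.497 in the 5% animals too, where 135 genes differed. Blood as the whole cause is argued against by the 18 animals of the other 3 groups, whose erythroid level predicted a share of -0.092 of the run difference over the 1868 genes (95% jackknife interval -0.147 to -0.037), where blood as the cause needs a share near 1. The array medians of the 2 runs overlap (-0.027, the lowest of the later run less the highest of the earlier), which says nothing, because RMA makes the medians nearly equal. The runs of this group also sit in well rows of their own, so a batch of these rows and the runs cannot be told apart, and the design names no biological difference between them.

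Male-biased liver genes were lower on 5% protein at 4 weeks and the female-specific Cyp2c12 was higher, but the female-biased Cyp2c7 and Sult2a1 were lower too (-3.10 and -2.77), so the pattern is not a plain exchange of male for female genes. Sharing of signal between close gene copies was tested on 6 sex-biased genes outside large families, whose 4 week change had a mean size of 2.37 (95% bootstrap interval 0.461 to 4.61); Stac3, Hao2 and Hsd17b2 fell and Bcl6, Cux2 and A1bg did not pass, so it stays open for the others. A candidate explanation is delayed maturation, in which genes that rise with age on 20% protein stay low on 5%. With the 20% animals of 4 weeks divided into separate sets of 3 for the diet and the time effect, the covariance of these effects across genes was below 0 in 20 of 20 splits (correlations from -0.52 to -0.27). The male-biased Cyp2a2 and Cyp2c13, which did not pass between the diets at 4 weeks, rose over time on 5% (2.34 and 3.44). Anything else that all 20% animals at 4 weeks share would give the same result, and age, body weight and hormone levels were not measured here.

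Macrophage, matrix and stellate cell genes were lower on 5% protein at 4 weeks. An equal fall of all non-hepatocyte cells is argued against by the cholangiocyte markers. Their median lay above that of the macrophage markers by 0.658 (95% bootstrap interval 0.291 to 1.025, over genes and not animals). A lower share of most such cells stays open. Endothelial, stellate and T and NK medians were -0.20, -0.36 and -0.16. The interval of the cholangiocyte median (0.158, -0.168 to 0.432) includes a small fall, with Epcam at 1.55 and Onecut1 at -1.26. Dim probes are argued against by the 43 of 51 members brighter than the median gene, whose median change was -0.439 (-0.575 to -0.360). A change in the number or state of macrophages and stellate cells stays open and was not tested, as does a smaller amount of blood, since erythroid markers were lower as well.

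Of 352 checks of a single animal against the other 5 of its group (87 genes in 4 groups, and the array medians), 26 found an animal far off, where chance gives about 17.6, or 1 in 20. Differences are log2 values from the mean of the other 5. On 20% at 1 week, animal 53 made up 8 of them, with Cyp2c13 (-5.79), Cyp2c11 (-5.11), Hao2 (-3.81), H19 (-2.38), Scd (-2.01), Car3 (-1.72), Spink1l (-1.70) and Hao1 (-0.56). Without it, the 1 week diet effect was -4.01 for Cyp2c11 and -3.42 for Hao2, and 282 genes were higher and 387 lower. In the same group animal 77 stood apart in Stac3 (1.56), animal 51 in Tp53inp1 (-0.89) and animal 78 in Cbs (-0.38). On 20% at 4 weeks, animal 30 stood apart in Ugt2b (-5.68), Pex11a (-1.24), Loxl2 (0.40) and Unc5b (0.36), and animal 29 in Dhrs7l1 (-0.81), Cyp2c11 (-0.56) and Scd (-0.25). On 5% at 1 week, animal 49 stood apart in Hao2 (2.81), Nox4 (1.37) and Acot2 (-0.67), animal 54 in Xdh (0.60) and its array median (0.056), animal 76 in Pck1 (-1.17), and animal 50 in Cyp2c12 (0.31). On 5% at 4 weeks, animal 23 stood apart in Ppargc1a (-1.23).

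The diet effect differed between 4 weeks and 1 week, by limma's test of the difference, for 38 of the 87 genes named by the rule (adjusted p from 2.09e-12 to 0.0482, values as the 4 week minus the 1 week log2 change). The share over all 17245 genes was 5.75%, but the 2 shares cannot be compared. Acot1, Gsta3, Ccdc92, C1h11orf86, Stac3, Mup5, Dhrs7l1 and Nox4 were named because this same test called them. Many others were named for a small p or a large change in a comparison of the same animals. More positive at 4 weeks were Acot1 (4.88), Gsta3 (3.64), Ccdc92 (3.38), C1h11orf86 (3.35), Cyp2c12 (2.84), Abcc3 (2.52), Unc5b (2.24), Abcd2 (2.07), Serpina7 (2.03), Trib3 (1.96), Acot2 (1.78), Slc7a1 (1.36), Gadd45a (1.34), Aldh18a1 (1.20), Lonp1 (1.17), Hadhb (0.66), Clpp (0.56), Rps19 (0.47), Rplp0 (0.40) and Gstm1 (0.35). More negative were Stac3 (-6.52), Mup5 (-4.91), Dhrs7l1 (-4.52), Nox4 (-3.50), Spink1l (-3.27), Aspg (-2.63), Orm1 (-2.34), Slc2a5 (-2.25), Cyp3a9 (-2.17), Xdh (-1.07), Hal (-1.05), Lrp1 (-0.91), Stat2 (-0.72), Sparc (-0.72), C1qa (-0.69), Lipc (-0.69), Itih1 (-0.68) and Msr1 (-0.46). Of the genes named only as examples, which were picked after their values were seen, Crat (1.77), Abcc4 (1.465), Vldlr (1.42), Pnpla2 (0.97), Idh3a (0.62) and Cs (0.435) were more positive by this test, and Hlf (-1.26), Slc27a5 (-1.24), Acox2 (-0.997), Pxmp2 (-0.91), Pc (-0.78), Baat (-0.505) and Cdh5 (-0.36) more negative.

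It also differed for 22 lists by camera at the preset correlation (adjusted p from 4.00e-11 to 0.0466), of which mitochondrial biogenesis alone held with an estimated correlation. The cell cycle list was at 0.052 and not called without the later run's 20% animals at 1 week (adjusted p = 0.727). The median differences upwards were those of ATF4 targets (0.55), glutathione and NRF2 targets (0.52), cell cycle (0.46), ribosomal proteins (0.40), cholangiocyte markers (0.34), mitochondrial biogenesis (0.26) and PPARa targets (0.16). Downwards were sex-biased genes (-0.68), interferon response (-0.53), matrix (-0.44), periportal markers (-0.40), amino acid breakdown (-0.40), fatty acid synthesis (-0.36), lipoprotein assembly (-0.34), macrophage markers (-0.29), acute phase genes (-0.26), T and NK cell markers (-0.26), xenobiotic P450 (-0.23), plasma proteins (-0.22), gluconeogenesis and glycolysis (-0.18), endothelial markers (-0.17) and one-carbon metabolism (-0.16).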

How the results depend on the processing

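Leaving out 1 run's animals from the 20% group at 1 week was chosen after seeing the data, and the other alternatives before. The 6 lists of peroxisomes, PPARa targets, fatty acid oxidation and respiratory chain at 1 and 4 weeks were counted apart. Over all alternatives, those with 1 animal left out included, 4 of their results reversed, 12 gained a call and 5 lost it. Alternatives other than leaving out 1 animal were compared 3947 times with the named genes and the other lists. Of these, 3669 kept direction and side of the threshold, 175 lost the call, 95 gained one and 8 reversed. For lists, reversed refers to the direction of camera's test, and in 4 of the 8 the median kept its sign. Leaving out 1 animal kept 5946 of 6144, with 123 lost, 75 gained and 0 reversed. All counts, overlaps and the 6 lists of peroxisomes, PPARa targets, fatty acid oxidation and respiratory chain at 1 and 4 weeks stayed within 1.5 times or on their side of the threshold under quantile normalization, centring, the offset, the mean of probe sets, the filter of low genes, trend and robust estimation, and well column. Signal over background limits the dim genes, and no background measure was used here.

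With every probe set tested, which adds probe sets that name no gene or several, 793 were higher at 1 week (main 321), 3636 at 4 weeks (2308) and 651 at both (240), 18 lists passed at 1 week (10), and peroxisomal enzymes passed there (-0.031, adjusted p = 0.0373). Array weights gave 952 and 588 genes for diet by time (611 and 380) and 421 lower on 20% over time (259). Fitting only the 2 groups, with fewer samples, gave 117 higher on 20% over time (176). With well row as a random block, 168 were higher and 168 lower at 1 week, 136 and 122 at both times, and on 20% over time 81 were higher and, rounded, 1.2e+02 lower (176 and 259). With run as a covariate, diet by time had 311 and 175 genes, and complexes II to V passed at 4 weeks (0.061, adjusted p = 0.0462). The cause was not tested. The estimated correlation left 2 lists at 1 week, 4 at 4 weeks and 1 for diet by time (22), and neither peroxisomal enzymes (-0.22, adjusted p = 0.516) nor PPARa targets (0.24, adjusted p = 0.462) passed at 4 weeks. fry called 6 lists at 1 week, 25 at 4 weeks (19 in the main setting) and 7 for diet by time.

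Each run alone holds fewer animals, with the spread estimated within group and run. In the second run 494 and 812 genes and 20 lists were called at 1 week, with PPARa targets (0.085), fatty acid oxidation (0.093), complex I (0.14, reversed) and complexes II to V (0.24) passing, unfolded protein response at -0.37 (direction of the test reversed, main median -0.053), and amino acid breakdown at 0.019, reversed and not called (adjusted p = 0.744). In the fourth run 696 and 768 genes and 18 lists were called, with peroxisomal enzymes at -0.22, complex I at -0.24 and complexes II to V at -0.22 (reversed). In the first run 1434 and 1300 genes were called at 4 weeks, peroxisomal enzymes did not pass (-0.14) and complexes II to V did (0.16). In the third 1178 and 946 were called, and PPARa targets did not pass (-0.047). Without the second run's 20% animals, 18 lists passed at 1 week, peroxisomal enzymes at -0.20, complex I at -0.24, complexes II to V at -0.21 (reversed) and fatty acid synthesis at -0.31 (direction of the test reversed, main median -0.064). Diet by time then had 235 lower genes, complex I at 0.20 (direction of the test reversed, main median 0.005) and fatty acid synthesis at 0.10 (reversed, not called), and 484 genes were lower on 20% over time. Without the fourth run's 20% animals, 503 and 733 genes were called at 1 week, complex I was 0.11 (reversed), complexes II to V 0.26 and unfolded protein response -0.28 (direction of the test reversed, main median -0.053). Diet by time then had 1198 and 603 genes, complexes II to V at -0.16 and unfolded protein response at 0.28, both reversed, and 293 and 695 genes moved on 20% over time. Apart from the fewer animals, the cause was not tested.

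With 1 animal left out, 213 to 354 genes were higher at 1 week and 205 to 448 lower (213 and 205 without 5% animal 74, 277 lower without 76), and 150 to 294 were lower at both times (150 without 74). Diet by time had 360 to 890 higher and 219 to 519 lower. The values without 5% animals of 4 weeks were 365 and 227 (31) and 360 and 219 (32), without 20% animals of 4 weeks 394 and 238 (72) and 386 and 233 (73), and 247 lower (67). Among 1 week animals they were 239 (50), 245 (52) and 242 (54) lower. Over time on 20%, 113 to 229 were higher and 151 to 338 lower, with 113 and 151 without 67, 113 and 162 without 73, and 169 lower without 72. Over time on 5%, 403 to 901 were higher and 386 to 754 lower (lowest without 32). Peroxisomal enzymes ranged from -0.10 to -0.005 at 1 week (passing without 20% animal 52, -0.06, adjusted p = 0.0437) and from -0.27 to -0.19 at 4 weeks (not passing without 5% animal 23, -0.19, adjusted p = 0.0793).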

Other observations

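Bile acid genes moved in both directions at 4 weeks. Of 23 measured, 5 rose and 11 fell (5 and 12 adjusted over the list alone), and the list did not pass (adjusted p = 0.121). The 6 named here were picked after their values were seen. The uptake carriers Slc10a1 and Slco1b2 changed by -0.35 ± 0.12 and -0.70 ± 0.19, and the conjugating enzymes Slc27a5 and Baat changed by -1.34 ± 0.23 and -0.64 ± 0.10. The efflux pumps Abcc3 and Abcc4 rose by 3.50 ± 0.20 and 1.85 ± 0.16. The IGF axis also went both ways, 5 up and 4 down of 16 (5 and 4 adjusted over the list alone), with Igfbp2 up by 3.07 ± 0.30 and Igfbp3 down (-1.20 ± 0.16), and the list did not pass (adjusted p = 0.980). In triglyceride storage and lipolysis 7 of 23 rose and 5 fell (9 and 5 adjusted over the list alone, list adjusted p = 0.116). The lipase gene Pnpla2 rose by 1.28 ± 0.14 and the lipid droplet genes Plin2 and Plin5 by 0.62 ± 0.13 and 0.81 ± 0.17. In fatty acid synthesis 1 of 18 rose, Me1, and 5 fell (1 and 5 adjusted over the list alone, list adjusted p = 0.121), with Thrsp at -2.00 ± 0.47. That list was at -0.58 in the first run (adjusted p = 0.00701) and 0.26 in the third (adjusted p = 0.388).

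In the citric acid cycle 4 of 16 rose and 1 fell at 4 weeks (5 and 2 adjusted over the list alone, list adjusted p = 0.0871; 0.149 in the first run and 0.0440 in the third), with Idh3a up by 0.75 ± 0.12, citrate synthase, Cs, by 0.50 ± 0.09, and pyruvate carboxylase, Pc, at -0.47 ± 0.13. Autophagy genes went both ways, 5 up and 7 down of 24 (5 and 8 adjusted over the list alone, list adjusted p = 0.636), with Map1lc3b at 0.46 ± 0.11 and Gabarapl2 at -0.55 ± 0.13. Of 14 clock genes 1 rose and 3 fell (1 and 3 adjusted over the list alone, list adjusted p = 0.325), Bmal1 at 1.67 ± 0.62, Per2 at -1.84 ± 0.65 and Hlf at -1.57 ± 0.27. The clock list was at -1.13 in the first run (2 rose and 7 fell, adjusted p = 0.0387) and -0.13 in the third (adjusted p = 0.826, with 0 called by limma). Per2 also differed between these runs on 20% (-2.78, adjusted p = 0.0125), and the runs hold unequal numbers of each diet, so diet and run are mixed in these clock values. Of 11 endothelial markers 4 fell (5 adjusted over the list alone), with Cdh5 at -0.47 ± 0.07, and the list narrowly missed the threshold (adjusted p = 0.0510; 0.334 in the first run and 0.00168 in the third).

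Splits of the animals at random asked whether chance alone gives as many called genes. For diet at 1 week the real count was 741 and the highest of the other splits gave 93, and 1 of 100 splits, the real one, was as large. For diet at 4 weeks it was 4455 against 2861 (1 of 100), where the highest moved 1 animal of each diet, for diet by time 991 against 225 (1 of 100), and for time on 5% 1429 against 8 (1 of 100). For the diet at both weeks and for time on 5%, this argues against a chance division of the animals, with 1% the smallest share that 100 splits can give. The splits cannot tell diet from well row at 1 week, or time from run, and diet and run are partly mixed at 4 weeks. For diet by time no conclusion on chance is drawn, because its splits exchanged the diets within each week. That removes the diet effects themselves, not only their difference, and adds them to the spread. For time on 20% the real count was 435 and 4 of 100 splits were as large, with 1291, 900 and 530 genes in the other 3. That share is small, but the other 3 splits gave more genes than the real one. Those with 1291 and 900 genes nearly follow the runs of animal numbers, which is a structure of these samples. The splits therefore do not single out time on 20%, and no conclusion on chance is drawn there. With run as a covariate within each week, 458 genes were called over time on 20%, and 375 of them were among the 435.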
